A study of Mus musculus with 6 samples.

How the data were processed

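Total RNA of sorted Lin-/cKit+/eYFP+ bone marrow cells from Srsf2 P95H/+ and Srsf2 +/+ mice, 3 libraries each, was depleted of ribosomal RNA, made into libraries with a stranded kit and sequenced as paired reads, per the labels. The authors name Trim Galore and cutadapt, STAR 2.5.3a, Picard 1.96, featureCounts of Subread 1.5.1, edgeR and limma, and the build mm10, without the role or settings of each, so that the strand setting of the counting is not known. The deposited count table holds raw counts for 26027 genes in the 6 libraries. The authors' CPM tables hold counts scaled to a common library total, and they were checked against the counts. CPM of the unfiltered table equalled each count divided by its library's total within 5e-04, and those of the filtered table the count divided by the total of its 15466 genes. These are the genes above 1 CPM in at least 2 libraries, and they hold 99.74% to 99.8% of the counts. All results start from the raw counts, and CPM given in the text are scaled by the library's whole total.

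Of the symbols in the counts, 24 had been turned into dates and 63 were blank, and 44 of these were replaced by the symbol that GENCODE M21 gives for the same identifier. Coordinates, biotypes, overlaps and the GC content of transcripts came from GENCODE M21 for mm10, which holds 25878 of the 26027 identifiers. Overlapping genes on the other strand and close paralogs can share reads. Besides those named in the results, Xist, Ezh2, Txnip, Mt2, Alas1, Selp, Plk1, Hist1h2an, Irf1, Cdkn1a, Sf1 and Clk3 have an annotated gene on the opposite strand. Overlaps of genes named from the 4-library comparison alone were not listed.

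Genotypes were compared with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr on genotype, robust quasi-likelihood fits and a two-sided F test, adjusted over all tested genes by Benjamini-Hochberg with a threshold of 0.05. SE of a log2 fold change follows from its F statistic. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Of 24 lists fixed before the data were examined, 23 with at least 5 tested members entered the adjustment, and the sex-linked control list was left out because sex is not balanced between genotypes. fry of limma gives a p for whether a list's genes move on balance one way, used here, and a mixed p for change in either direction, and neither compares the list with other genes.

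The tests, lists, a first set of other settings and the rule for named genes were fixed before the data were examined. The rule takes the 12 largest fold changes in each direction among genes with an adjusted p under 0.05, a mean of at least 2 CPM and groups that do not overlap, without clone-like, pseudogene, immunoglobulin, T cell receptor and sex-linked symbols. With fewer than 5 such genes in a direction, the 5 with the smallest p are given as values, whether or not the groups overlap. Up to 4 members of each list past the test, or else the 2 with the smallest p, are also named, as are Srsf2, Ezh2, Bcor, Xist and Ddx3y. Ighg1, BC018473 and other genes outside the rule were named after their values were seen. The same rule, without the fallback, was applied to the 4-library comparison. Some genes that the rule takes are not reported here.

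The other settings fixed at that time were other scalings, filters and tests (DESeq2 1.42.0, limma voom with and without sample quality weights), sex, sex and age, or the replicate number in the model, leaving out each library, and an estimated correlation or fry for the lists. After the data were seen, fits without replicate 3 of both genotypes and with a GC correction were added. That correction is a natural spline with 4 degrees of freedom of each library's deviation on transcript GC content, used as an offset. The replicate numbers met a rule for pairing set in advance: deviations from group means correlated across genes above 0.1 for each number (0.372, 0.348 and 0.613). Deviations cancel out within a genotype, so a shift shared by the replicate 3 libraries favours positive values for numbers 1 and 2, paired or not. Wild-type replicate 1 with P95H/+ replicate 2, at 0.463, and wild-type replicate 2 with P95H/+ replicate 1, at 0.386, lay above the values of numbers 1 and 2 and below that of number 3, and genes are not independent replicates, so the blocked fit is given beside the unblocked one.

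Library totals ran from 10747941 to 23010510 counts. Counts were simulated for each gene on its own with its spread in these libraries, without a shift shared by the replicate 3 libraries. On these cleaner counts the 6-library fit found 5% of genes changed 2-fold and 77% of genes changed 4-fold, with 5 false calls among 87. The 4-library fit found 81% and 98%, with 22 false calls among 201. The GC correction took a simulated GC trend of 0.9 to 0.02.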

Results

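RNA was sequenced from Lin-/cKit+/eYFP+ cells, described by the labels as immature haematopoietic multipotent progenitors, that were sorted from the bone marrow of tamoxifen-treated C57BL/6 mice. All mice carried hScl-CreERT, a tamoxifen-inducible Cre, and R26eYFP, a reporter that marks recombined cells. The groups were 3 libraries from Srsf2 P95H/+ mice and 3 from Srsf2 +/+ (wild-type) mice. Srsf2 encodes an SR protein that binds exonic RNA and takes part in splice site choice, and the P95H substitution lies in a residue that is mutated in myeloid disease. Wild-type replicate 1 came from a female of 54 weeks, and the other 5 libraries came from mice of 32 weeks. Wild-type replicates 2 and 3 and P95H/+ replicate 3 were male, and P95H/+ replicates 1 and 2 were female. The labels give a sex and an age for each library and a sample number of its own, but do not say whether that number stands for a mouse. The replicates are treated here as separate mice, and if some were not, p-values measure only the spread between these libraries.

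Wild-type replicates 1, 2 and 3 held 23010510, 21104066 and 16842751 counts, and P95H/+ replicates 1, 2 and 3 held 21673761, 22614408 and 10747941. Genes with at least 1 count numbered between 22074 in P95H/+ replicate 3 and 24315 in wild-type replicate 1. Xist, the transcript of the inactive X chromosome, stood at 3736, 3198 and 3618 CPM (counts scaled to a common library total) in the 3 libraries labelled female and at 5.35, 4.63 and 7.63 CPM in the 3 labelled male. The Y-linked Ddx3y stood at 109, 36.0 and 26.1 CPM in the libraries labelled male and at 0.05 CPM or less in the others, which matches the labels.

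Replicate 3 of both genotypes stood apart from the other 4 libraries. Genes with a transcript GC content of at most 40% were lower in them by a median log2 difference of -0.88 in wild-type replicate 3 and -1.13 in P95H/+ replicate 3, while genes above 55% were higher by 0.47 and 0.76. In the other 4 libraries these medians lay between -0.08 and 0.08. The first principal component of log2 CPM, which held 61.6% of the variance, placed wild-type replicate 3 at 48.7 and P95H/+ replicate 3 at 81.8, against -36.1 to -24.3 for the others. Gm26917, a noncoding RNA gene within ribosomal RNA sequence on chromosome 17, took 4.81% and 5.83% of the counts of the replicate 3 libraries and 2.72% to 3.06% of the others. Mpo, the myeloperoxidase gene of granulocyte precursors, stood at 6370 CPM in wild-type replicate 3 and 5340 CPM in P95H/+ replicate 3. The other 4 libraries held 4010 to 5220 CPM, so that P95H/+ replicate 3 lay barely above them. Of the same neutrophil list, Elane was at 2340 and 1800 CPM in these replicate 3 libraries, against 1020 to 1610 CPM. Ctsg, at 850 and 555 CPM there against 668 to 979 CPM, was not higher.

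**Figure D1:**
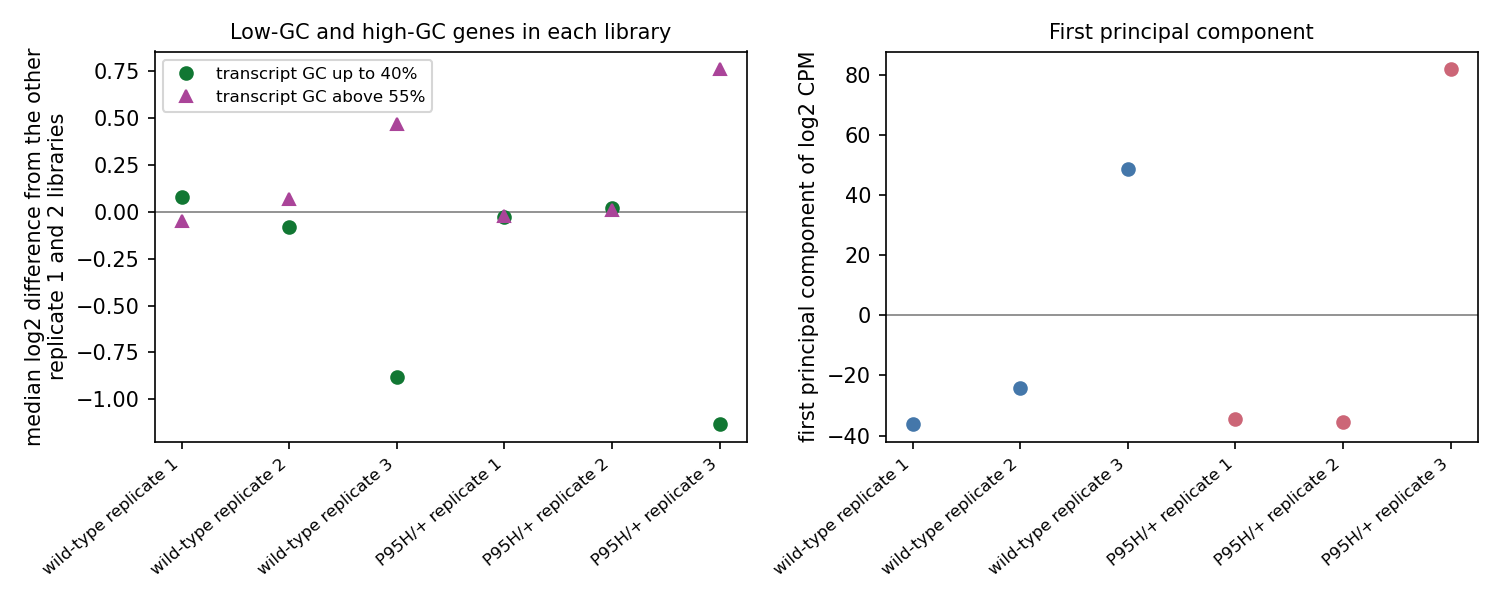
Left, median log2 difference of genes with low (circles) and high (triangles) transcript GC content in each of the 6 libraries; right, position of each library on the first principal component of log2 CPM, wild type in blue and P95H/+ in red. Replicate 3 of both genotypes lies at 48.7 and 81.8 on the component and shows low-GC medians of -0.88 and -1.13.

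The comparison of P95H/+ with wild-type progenitors asks which transcripts differ in cells that carry 1 mutant Srsf2 allele. Srsf2 itself (ENSMUSG00000034120, mm10 chromosome 11, 116849901 to 116853094, minus strand, protein coding) was at 331 ± 14.2 CPM in P95H/+ and 332 ± 9.79 CPM in wild type (SD, n = 3 each). Its log2 fold change was 0.07 (SE 0.17), with an adjusted p of 1. The sign of this value turned to -0.01 when libraries were scaled by total counts alone. Counts per gene do not show the base change itself, and Mettl23 and Mfsd11 overlap the gene on the other strand, so that reads of these genes could enter its count if counting was unstranded, which is not stated.

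With all 6 libraries, the differences with the smallest p among named genes were higher levels in P95H/+ of Tjp1, Aff2, Tmem215, Grb10 and Hist1h1t and lower levels of Msrb3, Nkx2-3, Scube3, Rab6b and Lax1, and none of these 10 passed the test over all genes. Msrb3, a methionine sulfoxide reductase, stood at 1.61 ± 0.355 CPM in P95H/+ and 6.25 ± 0.8 CPM in wild type (SD, n = 3 each), a log2 fold change of -1.90 (SE 0.29). Nkx2-3, a homeobox transcription factor, stood at 6.49 ± 0.345 and 15.9 ± 1.95 CPM, a log2 fold change of -1.22 (SE 0.22). Tjp1, a tight junction scaffold protein, stood at 11.8 ± 1.26 CPM in P95H/+ and 3.99 ± 1.16 CPM in wild type, a log2 fold change of 1.63 (SE 0.28). Grb10, an imprinted adaptor of growth factor receptors, stood at 61.3 ± 1.15 and 39.0 ± 4.82 CPM, a log2 fold change of 0.73 (SE 0.19). Each of the 10 had every P95H/+ library on one side of every wild-type library, which a choice by the smallest p favours.

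The other 6 had log2 fold changes of 1.73 for Aff2, 1.35 for Tmem215, 1.03 for Hist1h1t, a linker histone with close paralogs, -1.42 for Scube3, -1.24 for Rab6b and -1.11 for Lax1, an adaptor protein of lymphocyte signalling. On mm10, Msrb3 (ENSMUSG00000051236) lies on chromosome 10 at 120781096 to 120899101, Nkx2-3 (ENSMUSG00000044220) on chromosome 19 at 43612325 to 43615892, Tjp1 (ENSMUSG00000030516) on chromosome 7 at 65296165 to 65527781, and Grb10 (ENSMUSG00000020176) on chromosome 11 at 11930508 to 12038683. All 4 are protein coding. Tjp1, Msrb3, Aff2 and Scube3 are overlapped by annotated genes on the opposite strand.

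Of 17144 genes tested with edgeR's quasi-likelihood F test (two-sided), 0 passed an adjusted p of 0.05, and 361 had an unadjusted p under 0.05. The smallest adjusted p was 0.253, for Ighg1, an immunoglobulin heavy chain constant gene that stood at 2.63, 5.70 and 6.23 CPM in P95H/+ and at most 0.19 CPM in wild type. DESeq2 called 8 genes, higher Tjp1, Aff2, Ighg1, Ighv1-18 and Ighv1-15 and lower Msrb3, Nkx2-3 and Scube3, with 332 genes at an unadjusted p under 0.05. limma voom called 0 genes, with 362 at an unadjusted p under 0.05, and voom with sample quality weights called 97 genes, 20 higher and 77 lower, giving the replicate 3 libraries weights of 0.26 and 0.17 against 1.46 to 3.28 for the others. A fit with the replicate number as a block called 1 gene, Ighg1, at an adjusted p of 0.0211, and the fit without wild-type replicate 3 called 1 gene, the lower BC018473. The groups did not overlap for 1344 genes, 7.8% of those tested, where chance gives 10%. An exact permutation test of 3 libraries against 3 cannot give a two-sided p below 0.1 for a single gene.

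**Figure D2:**
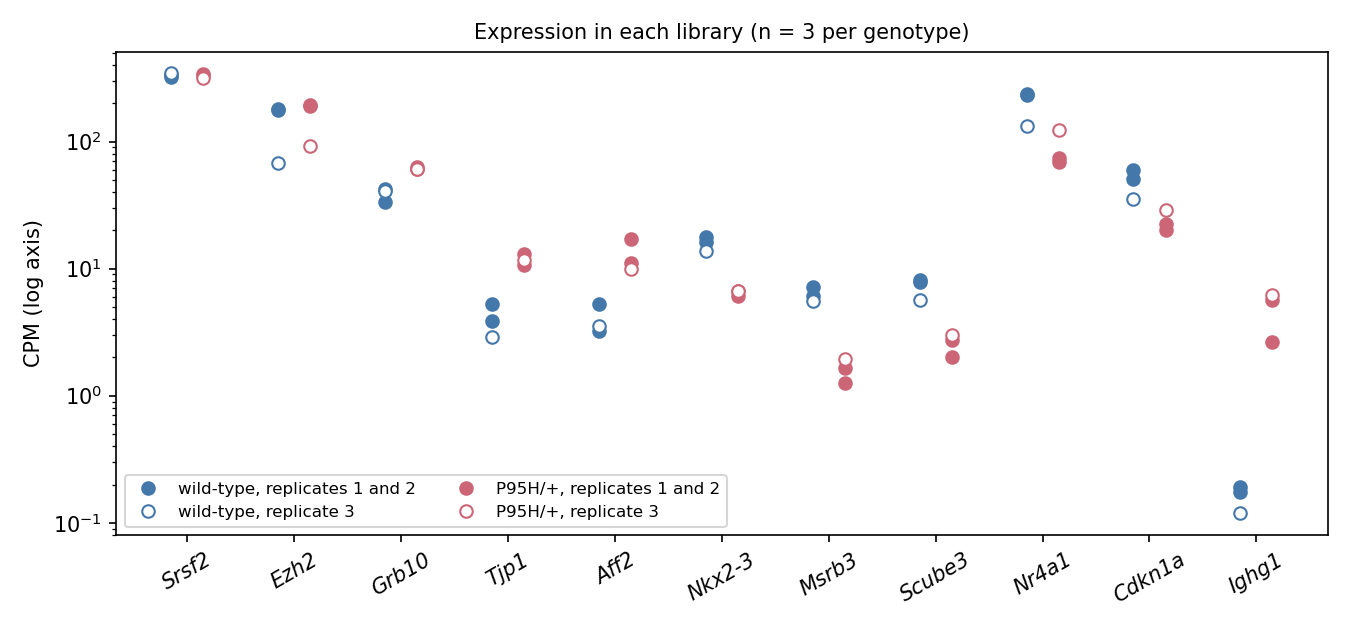
CPM on a log axis of 11 genes in each of the 6 libraries, wild type in blue and P95H/+ in red, with replicate 3 as open circles. Every P95H/+ library lies above every wild-type library for Grb10, Tjp1, Aff2 and Ighg1 and below them for Nkx2-3, Msrb3, Scube3, Nr4a1 and Cdkn1a, while Ezh2 lies at 68.1 and 91.8 CPM in the replicate 3 libraries of the genotypes.

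Gene lists fixed before the data were examined were compared between the genotypes. Taking all 6 libraries, 9 of 23 lists passed limma's camera with a preset correlation of 0.01, and in each of these lists 0 members passed over all genes and 0 adjusted over the list alone, as in the other 14. All 9 calls were lost with an estimated correlation, each at adjusted p = 0.943 with an estimated correlation, and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, gave an adjusted p of 0.984 for each. The replicate block kept 8 of these lists and lost the lymphoid list, at an adjusted p of 0.0803. With sex in the model the lymphoid (0.835), immediate early (0.28) and histone (0.18) calls were lost. With sex and age in the model, wild-type replicate 1, the only older mouse, sets the age term. The P95H/+ females set the sex term, so that P95H/+ replicate 3 alone is compared with wild-type replicates 2 and 3. In that fit the stem cell, lymphoid, T and NK cell and immediate early lists turned direction. The NF-kB and cell division calls ended there. The adjusted p of that fit rest on that single library, and they are given only with the other settings below.

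Markers of the stem cell and multipotent progenitor list were lower in P95H/+, with 19 of 24 tested members below wild type and a median log2 fold change of -0.34 (camera adjusted p 0.00197). Pdzk1ip1 stood at 5.81 ± 0.61 CPM against 9.74 ± 0.93 CPM (SD, n = 3 each), and Txnip, a thioredoxin-binding protein, at 145 ± 19.1 against 204 ± 26 CPM. The list of lymphoid priming and early B cell genes was lower as well, with 16 of 25 members negative and a median of -0.12 (adjusted p 0.0365). Rag1, a recombinase of antigen receptor rearrangement, had a log2 fold change of -1.01 (SE 0.56). The T and NK cell list, a marker of cells the lineage depletion should remove, was lower with 13 of 14 members negative and a median of -0.60 (adjusted p 1.64e-05), from low levels such as 0.575 ± 0.179 against 1.84 ± 0.792 CPM for Trbc1, a T cell receptor constant gene with a close paralog. Ncr1, a receptor of NK cells, had a log2 fold change of -1.82 (SE 0.83). Nkg7, the 1 positive member at 0.18 (SE 0.32), stood well above the rest of that list, at 137 to 297 CPM. Between the means of replicates 1 and 2 the medians were -0.41 for the stem cell, -0.62 for the lymphoid and -0.72 for the T and NK cell list, while in replicate 3 all 3 were positive, at 0.16, 0.96 and 0.12. After the GC correction the replicate 3 medians were 0.09, 0.96 and -0.04. The calls were lost with an estimated correlation, at adjusted p = 0.943 each. The stem cell call was lost without wild-type replicate 1, the only library from a mouse of 54 weeks, at a camera adjusted p of 0.592. It was also lost without P95H/+ replicate 1, at 0.117. Mean log2 CPM of this list overlapped between genotypes. It was 4.68, 4.27 and 3.84 in wild-type replicates 1, 2 and 3 and 3.85, 4.19 and 4.04 in those of P95H/+. The lymphoid call was lost without wild-type replicate 2 (0.808, with the direction turned), P95H/+ replicate 1 (0.6) or P95H/+ replicate 2 (0.792).

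The immediate early and heat shock list was lower in P95H/+ with all 6 libraries, with 21 of 29 members negative and a median of -0.21 (camera adjusted p 0.00197, and adjusted p = 0.943 with an estimated correlation). Its median was -0.50 between the means of replicates 1 and 2 and turned to 0.50 in replicate 3, or 0.20 there after the GC correction. Its orphan nuclear receptors Nr4a1 and Nr4a2 stood at 89.1 ± 30.3 against 199 ± 58.5 CPM and at 21.4 ± 2.77 against 39.6 ± 14.3 CPM (SD, n = 3 each). The NF-kB and inflammatory list had 20 of 30 members negative and a median of -0.24 (adjusted p 0.00197, and adjusted p = 0.943 with an estimated correlation), among them Traf1, a TNF receptor adaptor, at a log2 fold change of -1.05 (SE 0.28) and Il1r1, the interleukin 1 receptor, at -0.75 (SE 0.23). The NF-kB median was -0.38 between the means of replicates 1 and 2 and 0.03 in replicate 3. The immediate early call was lost without P95H/+ replicate 1 (adjusted p 0.603) or P95H/+ replicate 2 (0.0666), and the NF-kB call without wild-type replicate 1 (0.181) or P95H/+ replicate 1 (0.117).

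Neutrophil and erythroid genes were higher in P95H/+ with all 6 libraries, by a median log2 fold change of 0.36 in each list. The neutrophil list had 29 of 30 members positive and the erythroid list 30 of 33 (adjusted p 0.00611 for both, and adjusted p = 0.943 with an estimated correlation). The granulocyte receptor genes Cxcr2 and Csf3r had log2 fold changes of 0.62 (SE 0.38) and 0.46 (SE 0.32), and Mt2, a metallothionein of the erythroid list, of 1.00 (SE 0.42). These shifts lay largely in replicate 3, where the neutrophil median was 0.74 and the erythroid median 0.72, against 0.04 and 0.19 between the means of replicates 1 and 2. Without P95H/+ replicate 3 the directions turned, with adjusted p of 0.221 for the neutrophil list and 0.0335 for a lower erythroid list. The neutrophil call was also lost without wild-type replicate 2 (0.808) and the erythroid call without wild-type replicate 1 (0.463).

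Cell division genes were slightly higher in P95H/+, with 33 of 40 members positive and a median of 0.14 (adjusted p 0.00197, and adjusted p = 0.943 with an estimated correlation). The mitotic kinases Plk1 and Bub1b had log2 fold changes of 0.50 (SE 0.29) and 0.27 (SE 0.19). This list's median was similar in both parts of the data, 0.14 between the means of replicates 1 and 2 and 0.17 in replicate 3, and its call was lost without wild-type replicate 1 (0.0652) or P95H/+ replicate 1 (0.163). Replication-dependent histone genes, whose transcripts lack poly(A) tails, were lower, with 53 of 55 members negative and a median of -0.31 (adjusted p 8.88e-06, and adjusted p = 0.943 with an estimated correlation). Hist1h2bp had a log2 fold change of -0.72 (SE 0.30) and Hist1h2an of -0.62 (SE 0.31), both among close paralogs. The histone median was 0.04 between the means of replicates 1 and 2 and -0.81 in replicate 3, and without wild-type replicate 3 the list leaned the other way at an adjusted p of 0.424.

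**Figure D3:**
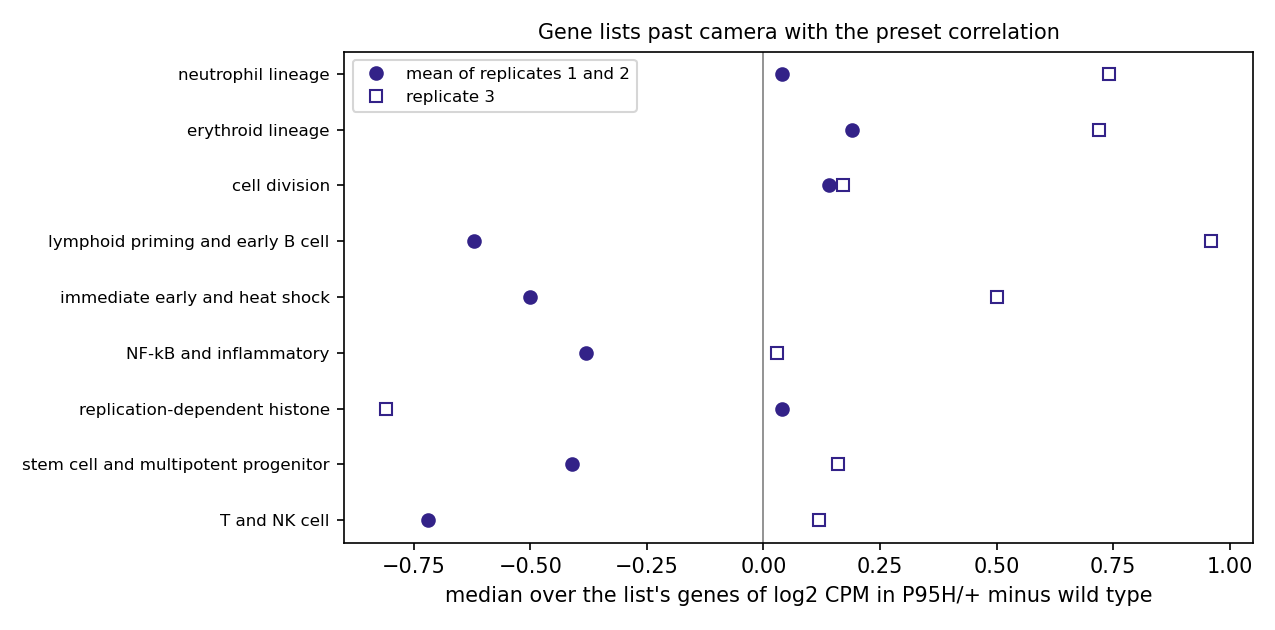
Median over each list's genes of log2 CPM in P95H/+ minus wild type, for the 9 lists past camera with the preset correlation, between the means of replicates 1 and 2 (filled circles) and between the replicate 3 libraries (open squares). The cell division medians are 0.14 and 0.17, while those of the lymphoid list are -0.62 and 0.96 and those of the histone list 0.04 and -0.81.

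The other 14 lists did not pass. Members of the monocyte, macrophage and dendritic cell list went both ways (adjusted p 0.758), with Flt1 at a log2 fold change of 0.63 (SE 0.27) and Adgre1, the F4/80 antigen, at -0.36 (SE 0.20). Heme biosynthesis (adjusted p 0.223), with Alas1 at 0.40 and Fech at 0.35, and the megakaryocyte list (0.342), with Gp1ba at 0.61 and Selp at 1.09, had positive medians of 0.15 and 0.09. The mast cell, basophil and eosinophil list (0.758) held Cpa3 at -0.66 and Cyp11a1 at 0.48. Interferon response genes (0.673) split between Irf1 at -0.54 and Oas1g at 1.37, and p53 targets (0.758) between Cdkn1a, the cell cycle inhibitor p21, at -0.95 and Eda2r at 1.13. The mature B and plasma cell list (0.915) held Tnfrsf13c at -0.81 and Igkc at 0.81. The stroma and endothelium list (0.884), whose median of -0.15 and mean of 0.11 differed in sign, held the collagen genes Col1a2 at 1.85 and Col1a1 at -1.24.

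Among lists tied to the mutation, SR proteins and spliceosome genes had a median log2 fold change of 0.05 (adjusted p 0.493), with Srrm1 at 0.39 and Sf1 at 0.30. The 8 genes reported as splicing targets of mutant SRSF2 had a median of 0.18 (adjusted p 0.579), with Clk3, an SR protein kinase, at -0.25. Ezh2, a histone methyltransferase whose splicing is altered by mutant SRSF2, stood at 159 ± 58.2 CPM in P95H/+ and 142 ± 64 CPM in wild type, and Bcor, a transcriptional corepressor, at 231.7 ± 67.4 and 207 ± 5.94 CPM (SD, n = 3 each). Their log2 fold changes, 0.22 (SE 0.44) and 0.24 (SE 0.25), turned to -0.11 without wild-type replicate 3 and to -0.05 without P95H/+ replicate 3. The MDS and MPN driver list had an adjusted p of 0.579, with Trp53 at 0.46. Ribosomal protein genes (0.0525), with Rps15a at -0.34 and Rps13 at -0.24, oxidative phosphorylation (0.802), with Ndufa10 at 0.48 and Sdhd at 0.22, and cholesterol synthesis (0.221), with Pmvk at -0.51 and Insig1 at -0.33, complete the lists. The ribosomal protein list was called lower in 9 and higher in 4 of 21 settings. With GC correction it was lower (camera adjusted p 0.047), and without P95H/+ replicate 3 it was higher (0.0184). Splicing itself cannot be read from counts per gene.

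Without replicate 3 of both genotypes, an alternative chosen after the depth and GC trend of these libraries were seen, 144 of 17371 genes passed edgeR's test in 2 against 2 libraries, 32 higher and 112 lower. Of the immediate early and heat shock list, Nr4a1 (log2 fold change -1.67, SE 0.08, adjusted p 1.09e-05), the AP-1 gene Fosl2 (-0.84) and the heat shock gene Dnajb1 (-0.74) fell in P95H/+ replicates 1 and 2. Cdkn1a of the p53 target list fell (-1.34), while that list did not pass (adjusted p 0.356). Of the lymphoid list, Dntt, the terminal transferase of early lymphocytes, fell at -1.24, Blk at -2.28 and Lax1 at -1.35, and Gimap4, in no list, fell at -2.18. The stem cell genes Prdm16 and Robo4 fell as well, at -1.07 and -1.31. Epx, Prg2 and Prg3, which encode eosinophil granule proteins, rose at 1.20, 0.96 and 1.03, and Ear6, one of a family of close paralogs, at 0.87. The mast cell, basophil and eosinophil list that holds the first 3 did not pass (adjusted p 0.392), with 11 members positive and 9 negative, 3 higher over all genes, and 3 higher and 1 lower, Prss34 at -0.52, adjusted over the list alone. Moreover, with all 6 libraries the values of Epx, Prg2 and Ear6 were -0.25, -0.05 and -0.17, while that of Prg3 was 0.12. The higher Hmga2 (1.29), Kcnq3 (1.19), Gja1 (0.74), Dpp7 (0.85), Dqx1 (1.31), Mgl2 (1.07) and Lyplal1 (1.54) passed too. Of the 10 genes named by smallest p with 6 libraries, Msrb3, Nkx2-3, Scube3, Rab6b, Lax1, Tjp1 and Grb10 passed here, in the same direction. These 4 libraries are part of those 6, so this adds no independent evidence. Aff2, Tmem215 and Hist1h1t did not pass, at adjusted p of 0.0695, 0.0793 and 0.0782. Ighg1 passed as well, with a log2 fold change of 4.51 (SE 0.51, adjusted p 0.00815).

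Further lower genes of the naming rule were St6galnac1, AI506816 (-3.58), Ly6d (-1.92), Npdc1 (-1.72), Adam11 (-1.67) and Erdr1 (-1.64). St6galnac1 had 0 counts in all P95H/+ libraries and also in wild-type replicate 3.

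In these 4 libraries 10 lists passed camera with the preset correlation. The immediate early and heat shock list was lower (adjusted p 1.46e-10), with 5 members lower over all genes and 22 adjusted over the list alone, as were the lymphoid list (1.79e-10, 4 and 17), the T and NK cell list (4.23e-07, 0 and 9), the NF-kB list (6.4e-06, 2 and 13) and the stem cell list (1.79e-05, 2 and 8). The stroma and endothelium list (0.0179, 1 and 3) and the mature B and plasma cell list (0.0234, 0 and 6) were lower too, while 1 member of the stroma list, Col1a2 at 1.46, was higher adjusted over the list alone. Their medians were -0.55 and -0.48 between the means of replicates 1 and 2, and 0.89 and 0.78 in replicate 3. Oxidative phosphorylation (1.69e-07), cell division (0.000191) and ribosomal protein genes (0.0234) were higher, with 0 members over all genes and 0 adjusted over the list alone. The oxidative phosphorylation median was 0.15 between the means of replicates 1 and 2 and -0.39 in replicate 3, and that of ribosomal protein genes 0.06 and -0.38, with 59 of 79 of the latter negative in 6 libraries. With an estimated correlation none of the 10 passed, at adjusted p from 0.825 to 0.956 with an estimated correlation.

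Of the 143 called genes with a known GC content, 55, or 38.5%, differed in the same direction between the replicate 3 libraries, against a median of 43.4% in random lists matched on expression and GC content. Of those called higher 19 of 32 kept their direction, and of those called lower 36 of 111. Epx stood at 343 CPM in wild-type replicate 3 and 150 CPM in P95H/+ replicate 3, and Nr4a1 at 132 and 124 CPM. The 4 libraries compare a female of 54 weeks and a male with 2 females, and a term for sex there leaves the 54-week female as the single wild-type library, so that sex, age and genotype cannot be separated in them.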

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

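The test of a genotype by sex term was chosen after the data were seen. Hist1h4m, a histone H4 gene with close paralogs, differed between the sexes in its difference between genotypes, by 9.18 on the log2 scale for that term (edgeR, all 6 libraries, adjusted p 0.0434). It stood at 75.6 CPM in the wild-type female and 2.58 and 1.5 CPM in the P95H/+ females, and at 2.27 and 2.67 CPM in the wild-type males and 37.4 CPM in the P95H/+ male. The term rests on a single wild-type female and a single P95H/+ male. This was the 1 gene that passed of all tested, with 1263 at an unadjusted p under 0.05, and 0 of the genes named in the text by rule passed.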

How the results depend on the processing

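The fits without replicate 3 of both genotypes, with or without sex there, and those with a GC correction were chosen after the data were seen. For the count of 0 genes, DESeq2 gave 8, voom with quality weights 97, the replicate block 1, the block with GC correction 1, and leaving out single libraries 0 to 1, the 1 without wild-type replicate 3. Without both replicate 3 libraries the count was 144, with GC correction 151 (132 shared) and with sex 589 (141 shared), where wild-type replicate 1 alone stands for its genotype and is taken to vary like P95H/+. Other scalings, filters, voom, sex, sex and age, and GC correction alone gave 0. The 9 lists became 0 with an estimated correlation (adjusted p 0.943 each) and 0 with fry (0.984 each). Srsf2 was -0.01 with total counts alone, which shifted the median gene by -0.072.

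Of 1303 alternative values for 57 named genes, 1285 kept their sign. Most of these genes were chosen by a small p in these libraries, and the alternatives use the same libraries or part of them. A kept sign was therefore likely beforehand and adds no independent evidence. Ezh2 was -0.08 with sex, -0.33 with sex and age, and -0.11 to 0.49 leaving out single libraries, and Bcor -0.05 to 0.37. Sex and age, a fit in which P95H/+ replicate 3 alone stands for its genotype, turned Ncr1 to 0.46, Col1a1 to 0.45 and Clk3 to 0.06. Quality weights took Bcor and Fech to 0.00. Without both replicate 3 libraries Bcor was -0.05, 0.00 with GC correction and -0.03 with sex. With sex there, Xist was -0.09 and Cxcr2 -0.23. Rps15a was 0.02 with GC correction and 0.08 with sex there, and Rps13 0.01 and 0.12. With all 6 libraries Epx was -0.25, Prg2 -0.05 and Ear6 -0.17, while Prg3 kept its sign at 0.12.

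With sex and age, lists turned direction at adjusted p of 0.926 (stem cell), 0.0268 (lymphoid), 0.841 (T and NK) and 0.0268 (immediate early), and cell division (0.614) and NF-kB (0.926) calls ended. These adjusted p with sex and age rest on P95H/+ replicate 3 alone. They are printed as values, and no list is taken as changed on them. With sex the lymphoid (0.835), histone (0.18) and immediate early (0.28) calls ended. The lymphoid call also ended without a filter (0.106), with the block (0.0803) and with block and GC correction (0.0631). Without both replicate 3 libraries the histone list turned at 0.421, 0.193 with GC correction and 1.24e-05 with sex, and the neutrophil list at 0.0775 with sex. There the neutrophil call ended at 0.413, 0.532 with GC correction, and the erythroid call at 0.776, 0.936 with GC correction and 0.249 with sex. Leaving out single libraries gave 9.48e-07 to 0.808 for the lymphoid list, 9.22e-06 to 0.808 for neutrophil, 3.6e-09 to 0.463 for erythroid, 5.66e-19 to 0.424 for histone, 0.000129 to 0.592 for stem cell, 0.000404 to 0.163 for cell division, 2.92e-05 to 0.181 for NF-kB and 9.17e-08 to 0.603 for immediate early genes. The cause of these changes was not tested. Simulated 2-fold changes were mostly missed with 6 libraries (5% found).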

Other observations

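The tests of sex and of GC as the whole cause for the first pattern, and of the allele and of strain variants for the third, were chosen after the result was seen, as was the use of the random-list range in the test of swapped libraries.

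Transcripts of the switched immunoglobulin classes Ighg1, Igha and Ighg2c lay higher in every P95H/+ library than in every wild-type library, although none passed edgeR's test with all 6 libraries in the model without a block. Without replicate 3 of both genotypes Ighg1 passed (log2 fold change 4.51, adjusted p 0.00815), and Igha and Ighg2c did not (0.696 and 0.323). They were chosen after their values were seen. Ighg1, on chromosome 12, stood at 0.174, 0.190 and 0.119 CPM in wild-type replicates 1, 2 and 3 and at 2.63, 5.70 and 6.23 CPM in P95H/+. Igha, the IgA constant gene, stood at 99.3, 14.7 and 61.3 CPM against 177, 116 and 192 CPM, and Ighg2c at 2.26, 4.31 and 0.653 against 4.52, 8.45 and 29.1 CPM, while Ighg2b overlapped at 2.56 to 9.95 against 4.15 to 27.1 CPM. Jchain, which joins IgA and IgM multimers, overlapped between genotypes at 33.4, 8.34 and 9.26 against 51.7, 36.7 and 19.9 CPM, as did Sdc1, a surface marker of plasma cells, at 7.54, 7.65 and 10 against 8.40 to 11.4 CPM. Whether plasma cells remained in the lineage-negative gate was not tested.

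Replicate 3 of both genotypes departed together from the other 4 libraries. No labelled sex or age was theirs alone, as wild-type replicate 2 also came from a male of 32 weeks. A trend on transcript GC content as the whole cause is argued against, since after the GC correction a gap of 49.4 remained on the first principal component between these libraries (32.2 and 63.0) and the other 4, whose range was 10. As part of the cause it stays open, as the correlation across genes of the 2 libraries' deviations went from 0.61 to 0.40, between the bounds set for the test (0.3 and 0.5). A larger share of erythroid and neutrophil cells may contribute, with the smallest of the 4 medians of these lists in replicate 3 over replicates 1 and 2 at 0.25 after the correction and the largest at 0.93. Such a rise in P95H/+ replicate 3 was not particular to these lists, with 0.85 for the lymphoid and 0.80 for the stroma and endothelium list. In wild-type replicate 3 the medians of the latter lists were -0.53 and -0.39. Sex was not settled. The male wild-type replicate 2 lay 89.5 from the replicate 3 mean and 11.1 from the mean of the others, away from the other males. It is 1 library, however, and part of the pattern as first seen. The other males are the replicate 3 libraries that define the pattern, so that the test could hardly go against sex.

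More genes were called without replicate 3 of both genotypes than with all 6 libraries, 144 against 0. The 6-library fit with GC correction called 0 genes, so this correction did not bring the calls back. It left a gap of 49.4 on the first principal component, so a GC bias that it did not remove stays open. Swapped replicate 3 libraries might explain it: 38.5% of the called genes differed in the same direction there, under the bound of 40% set beforehand, but within the 36.4% to 51.0% of random lists. Against it, the median difference in the called direction was -0.14 there, where a swap would turn the 1.00 of the 4 libraries to a similar size below 0. The split with these labels exchanged called 0 genes and 12 lists, against 0 and 9 for the real labels. A count of 0 says little, as 6 libraries found 5% of simulated 2-fold changes. A single pair of libraries that stand apart leaves a swap open. The differences may follow sex and age together among the 4 mice, since the same -0.14 came from replicate 3 males of one age. Neither alone parts the wild-type mice, an older female and a male, from the P95H/+ females. Any other difference between these mice would give -0.14 as well, so that sex and age acting together and single mice stay open.

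On chromosome 11, 74.4 to 100.1 kb from Srsf2, 3 genes were on in wild-type replicates 1 and 2 and off in wild-type replicate 3 and all P95H/+ libraries. BC018473 stood at 123 and 106 CPM against 0.279 CPM or less, 683-fold higher in wild-type replicates 1 and 2 than in P95H/+, and St6galnac1 at 10.3 and 8.81 against 0 CPM, at least 173-fold higher with a floor of 3 counts over the P95H/+ libraries (0.055 CPM), with Gm11735 alike at 2.48 and 2.27 against 0 CPM. A lowering by the P95H allele would need wild-type replicate 3, where the highest of the 3 genes was at 0.12 CPM against at least 2.27 CPM in the other wild-type libraries, to carry the allele or to be off for another reason, and this single library does not exclude it. Strain variants around the targeted locus are a candidate explanation. Variants that act on their own chromosome would have to lie on both, since P95H/+ mice keep 1 untargeted chromosome and the genes were off. Outside 1 Mb of Srsf2, 11 genes were also on in some libraries and off in others. Of these, 1 pair, Trim5 and Trim12a, were neighbours within 100 kb, as in a share of 0.014 of random draws. They are close paralogs off in P95H/+ replicate 3, and show nothing of the locus beside Srsf2. A P95H/+ library labelled wild-type replicate 3 stays open, as it lay nearer to P95H/+ at 50% of the genes called in 4 libraries, short of the 60% set for such a label, while P95H/+ replicate 3 did at 45.1%, and it lay with wild type for Ighg1 (0.119 CPM), Msrb3 (5.52), Tjp1 (2.91) and Nkx2-3 (13.8), genes picked with this library counted as wild type.

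The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. For genes the real split called 0, which any of the 10 splits must reach, so the count says nothing of chance, and the highest other, the split of females from males, called 6. For lists, 6 of the 10 splits called as many as the real 9, and the highest other called 14. The 3 other splits that also part all 3 replicate numbers called 0 genes each and 12, 8 and 14 lists, while the remaining 6 keep libraries of 1 number together.

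Away from Srsf2, AI506816 on chromosome 5 stood at 255 and 294 CPM in wild-type replicates 1 and 2, 466 CPM in P95H/+ replicate 3 and 7.60 to 22.6 CPM in the other 3 libraries. Mid1 stood at 59.4 and 64.9 CPM in wild-type replicates 1 and 2 and 13.1 to 27.2 CPM in the other 4. Pydc3 was at 0.119 CPM in wild-type replicate 3 and 11.6 to 16.5 CPM in the other 5.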
